A study of Danio rerio with 10 samples.

How the data were processed

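Total RNA from zebrafish sperm, oocytes and embryos of 8 stages was isolated with TRIzol and made into libraries with the TruSeq RNA v2 kit, per the labels. Single reads of 50 bp were sequenced on a HiSeq2000. The values deposited by the authors are RPKM, reads per kilobase of gene scaled for the reads of the library, in 1 table with 1 column for each of the 10 libraries, neither log-transformed nor given a pseudocount. The submitters' processing notes list TopHat2 2.0.9 and the genome build Zv9. The counting tool, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Raw reads were not used here.

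Reads behind the values were worked back from the table. Within a gene, values of different libraries stand in ratios of whole numbers times 1 constant per library pair, so the worth of 1 read, the gene length and the reads to which each library had been scaled could be solved for. Of 32574 genes, 26476 had whole reads and a length recovered, which is 99.9% of the genes above 0 in at least 2 libraries. Of all deposited values above 0, including those of genes above 0 in only 1 library, 99.2% came out whole within a tolerance of 0.02 reads. The procedure was tested on simulated data of 1500 genes, where 99.9% had every read count recovered. The reads scaled to lay between 37762530 (1-cell) and 113972795 (4-cell), and reads in genes made up 86.3% to 93.8% of them. At these depths 3 reads in a gene of 1 kilobase amount to 0.026 RPKM in the 4-cell and 0.079 RPKM in the 1-cell library.

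Each stage has 1 library and forms its own group. The 6 comparisons were sperm against oocyte, 1-cell against oocyte, 128-cell against 1-cell, 1000-cell against 128-cell, sphere against 1000-cell and sphere against 1-cell. In each, genes with at least 1 RPKM in either library were measured, the change was the difference of log2(RPKM + 1), and a gene counted as changed at a difference of 2 or more in size. No p-value was computed for these, since 1 library per group leaves no replicate spread. Fold intervals are exact 95% Clopper-Pearson intervals on the recovered reads and cover counting error only. Against a library with no read the fold is a lower bound at a floor of 3 reads in that library.

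The trend over cell number used the 7 libraries from 1-cell to 1000-cell, whose labels give a number of cells. Genes with at least 1 RPKM in at least 2 of these libraries were fitted with limma 3.58.1 (lmFit and eBayes with trend) on log2(RPKM + 1) against log2 cell number, with 5 residual degrees of freedom, and called at a Benjamini-Hochberg adjusted p under 0.05. The test treats each stage as a draw around a straight line, so its error holds both departures from the line and differences between libraries. To see how many genes pass without a stage order, 100 orders, the real one among them, were fitted in the same way.

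A total of 25 gene lists were fixed before the data were examined: sperm axoneme and tail, meiosis, egg coat and oocyte factors, germ plasm and piRNA pathway, maternal axis and activation factors, first zygotic transcription factors and signals, mesendoderm and Nodal signalling, BMP, FGF and organizer signalling, and enveloping layer epithelium. Further lists were DNA methylation and demethylation, histone modifiers and remodellers, histone variants, cell cycle and replication, mRNA stability and maternal clearance factors, ribosomal proteins and mitochondrially encoded proteins. The rest were nuclear oxidative phosphorylation, proteasome, housekeeping references, heat shock and stress, follicle and steroidogenic cells, testis somatic cells, blood, muscle, and liver and yolk proteins. For lists with at least 5 measured members, the median change was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description and not a test. For 22 lists with at least 5 expressed members, the mean over the members was correlated with log2 cell number by Pearson's r and Spearman's rho. Expressed meant a mean of at least 1 RPKM over all 10 libraries, sperm and sphere included. Exact two-sided permutation tests ran over all 5040 pairings, with Benjamini-Hochberg adjustment over the 22 lists, and r was computed again without the 1-cell and 4-cell libraries, the 2 farthest from the median log2 cell number. Lists were matched by symbol. The name table gave a symbol to 20901 genes, and the 3270 genes that share a symbol with another gene are not named singly.

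The genes named were chosen by a rule fixed beforehand: in each comparison the 10 with a symbol that rose most and the 10 that fell most among those at 5 RPKM or more in the higher library, the list members past the rule or with the largest changes, the 5 most abundant genes of a library, and the 10 largest positive and negative slopes of the trend.

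Alternatives fixed before the data were examined were a pseudocount of 0.1 or 5, no filter on low values or at least 5 RPKM, rescaling each library to a total of 1000000, median ratio scaling, leaving out the 20 most abundant genes with the rest rescaled to a common total, and a 2-fold rule. For the trend they were each library left out in turn, 1-cell to 128-cell only, sphere added by stage rank and eBayes without trend. Added after seeing the data were genes with a symbol only, all libraries thinned to the reads of the 1-cell library, a library replaced by its neighbour in stage, limma-voom on the recovered reads, and the stages from 64-cell on. On the simulated data of a self-test, made from these libraries, the 4-fold rule recovered 143 to 166 of 200 genes changed 8-fold, 100% of those with a mean of at least 5, and called 0 unchanged genes. The trend recovered 189 of 200 genes with a slope of 0.5 and called 7 unchanged genes. That slope is steeper than the median of the called rising genes, 0.209. Noise was drawn for each gene separately, so the 7 does not cover differences that many genes of a library share. Work was done in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and in R 4.3.3.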

Results

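RNA was sequenced from zebrafish (Danio rerio) gametes and early embryos to follow gene expression through 10 stages. These were sperm, oocyte, embryos of 1, 4, 16, 64, 128, 256 and 1000 cells, and the sphere stage, a blastula stage that comes after the 1000-cell embryo. Each stage was represented by 1 library, so there was no replicate check, and every interval given here covers counting error only. The deposited values were RPKM (reads per kilobase of transcript, scaled for the reads of the library) for 32574 genes. The reads to which the values had been scaled, recovered from the values themselves, numbered 39600592 for sperm and 54662927 for the oocyte. For the embryos they numbered 37762530 at 1-cell, 113972795 at 4-cell, 71597079 at 16-cell, 72125930 at 64-cell, 93744349 at 128-cell, 60662759 at 256-cell, 71051833 at 1000-cell and 80204068 at sphere. Sperm held the most genes at 1 RPKM or more (16450) and the 1-cell embryo the fewest (8479), with 10005 in the oocyte and 13551 in sphere. Transcripts of the mitochondrial genome took 11.2% of the RPKM total in the 1-cell library, 8.01% in the oocyte, 3.49% in the 128-cell library and 3.18% in sphere. Across genes, which are not independent replicates, the Pearson r of log2 values was 0.96 between oocyte and 1-cell, 0.87 between 1-cell and 128-cell, 0.99 between 128-cell and 1000-cell, 0.96 between 1000-cell and sphere, and 0.65 between sperm and oocyte. Changes below are differences of log2(RPKM + 1) in genes with at least 1 RPKM in either library, and a gene counted as higher or lower at a difference of 2 or more (4-fold). Folds are ratios of RPKM with an exact 95% counting interval.

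**Figure D1:**
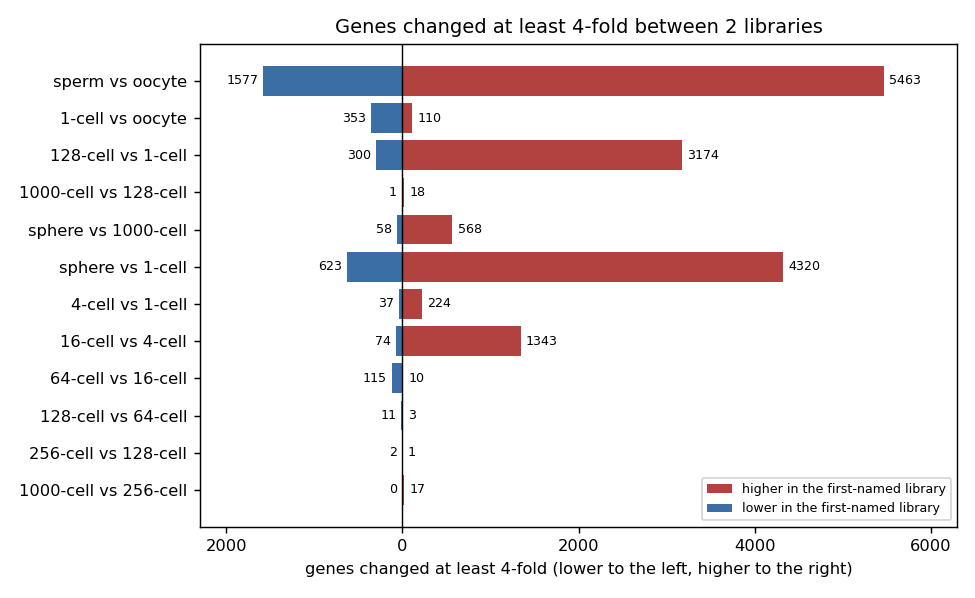
Number of genes at least 4-fold higher (bars to the right) or lower (bars to the left) in the first-named library of each comparison, out of the genes with at least 1 RPKM in either library. Sperm against oocyte gave 5463 higher and 1577 lower genes, and 1000-cell against 128-cell gave 18 and 1, with 1 library per stage.

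The sperm library was compared with the oocyte library to find what set the 2 gametes apart. The sperm library also held markers of testis cells other than germ cells, given below, so its values cannot be assigned to mature sperm alone. It held meiotic chromosome and recombination transcripts that the oocyte library lacked or nearly lacked. HORMAD1, a protein of meiotic chromosome axes, stood at 486 against 0.30 RPKM (1639-fold, 1126 to 2487). The synaptonemal complex genes SYCP1 and SYCP3 were 243-fold (218 to 272) and 137-fold (121 to 157) higher, and the meiotic recombinase DMC1, with no read in the oocyte, was at least 5938-fold higher. Axoneme and tail genes were also higher, with RSPH9, of the radial spokes, at 190 RPKM and at least 3940-fold above an oocyte library that held none of its reads. The oocyte in turn held the tight junction claudins cldnd (4558 against 0.65 RPKM, 7031-fold higher in the oocyte) and cldng (2459 against 1.86 RPKM). It also held the importin gene kpna7, birc5b, the cell adhesion gene epcam (2201 against 7.46 RPKM) and BTG4, an adaptor for mRNA deadenylation in oocytes (926 against 2.57 RPKM, 360-fold, 302 to 432). Maternal factors with a known part in activating the embryonic genome were lower in sperm, nanog 32.8-fold (31.2 to 34.4) and pou5f3 439-fold (328 to 601). So was the maintenance methyltransferase DNMT1 (27.4 against 1424 RPKM, 52.0-fold, 50.6 to 53.5).

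By list, 16 of 18 measured meiosis genes and 30 of 32 axoneme and tail genes were at least 4-fold higher in sperm, with median log2 changes of 5.91 and 5.85 against 1.22 for all 17364 measured genes. Both medians lay above all 10000 random lists of matched expression. The germ plasm and piRNA list had 12 higher and 3 lower of 20 members. Among the higher were PIWIL1, a piRNA-binding protein (413 against 2.02 RPKM, 204-fold, 186 to 224), and the germ cell helicase DDX4 (335 against 38.2 RPKM, 8.76-fold, 8.5 to 9.0). Of 30 egg coat and oocyte factors 18 were lower in sperm and 2 higher (median -2.96), and of 18 maternal axis and activation factors 9 were lower and 0 higher (median -2.31). Genes of housekeeping complexes also stood higher in sperm: 34 of 69 ribosomal protein genes, 40 of 81 nuclear genes of oxidative phosphorylation and 30 of 42 proteasome genes, with 0 lower in the first and the last of these. Histone variants were higher in 5 of 8, among them h2ax1 (675 against 37.4 RPKM, 18-fold, 17.2 to 18.9) and MACROH2A2 (222-fold, 130 to 418). Markers of testis cells other than germ cells were present in the same library, where 12 of 15 were at least 4-fold higher than in the oocyte, with a median of 101 RPKM. They included the Leydig cell hormone insl3 (430 RPKM, no read in the oocyte, at least 7305-fold), the Sertoli cell factor gsdf (312 RPKM), the steroidogenic gene STAR (233 RPKM) and the smooth muscle actin acta2 (168 RPKM). Follicle and steroidogenic genes, 5 of whose 15 gene IDs are also among the 15 of the testis list, were higher in 7 of 11 and lower in 1 (median 3.82). Markers of blood (median 0.68, 2 of 10 higher), muscle (1.58, 3 of 7 higher) and liver and yolk proteins (2.17, 7 of 11 higher) had median levels in sperm of 0.929, 0.471 and 0.505 RPKM. In all, 7040 genes differed at least 4-fold, 77.6% of them higher in sperm. Pancreatic protease genes such as prss59.1 (483 RPKM) and prss1 (431 RPKM) were also among the 10 with the largest changes.

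The 1-cell embryo was compared with the oocyte to see what differed around fertilisation. Among genes with a symbol, the largest differences between these libraries were transcripts lower in the 1-cell embryo. The lipid carrier gene apoeb stood at 154 RPKM in the oocyte and 0.11 RPKM in the 1-cell library (1366-fold, 719 to 2987). The keratin gene krt5 stood at 116 against 0.20 RPKM (572-fold, 366 to 951), krt91 at 72.6 against 0.093 RPKM (782-fold, 437 to 1567) and icn at 145 against 0.26 RPKM. The tetraspanin gene CD63 stood at 54.8 against 0.23 RPKM (243-fold, 136 to 488), and ANXA2, with no read in the 1-cell library, was at least 1069-fold lower. Whether these transcripts lay in the eggs or in other cells of the oocyte sample was not tested. The follicle and steroidogenic list had a median of 0.036 RPKM in the oocyte, with 3 of 15 gene IDs at 1 RPKM or more. Its mean log2 value over 10 expressed members was 1.48 in the oocyte and 1.45 in the 1-cell library. Other cell types are not covered by that list. Egg and maternal factors were within 4-fold: none of 28 egg coat and oocyte factors, 18 germ plasm genes or 15 maternal axis and activation factors passed the rule. In the enveloping layer list, the superficial epithelium of the embryo, 8 of 12 measured genes were lower and the median was -2.89, below all 10000 random lists. These 8 included krt4 (39.5 to 0.064 RPKM) and krt8 (37.5 to 0.41 RPKM, 91.2-fold, 68.1 to 125). Blood markers had a median of -1.91 over 5 genes, 2 of them lower. Nuclear genes of oxidative phosphorylation (median -1.05, 9 of 75 lower, 0 higher) and of the proteasome (median -1.21, 3 of 42 lower, 0 higher) lay below all 10000 random lists. The 13 mitochondrially encoded genes had a median of 0.44 and none passed the rule. Ribosomal proteins had a median of -0.12, which turned to 0.11 under median ratio scaling.

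Of 10373 measured genes, 353 were lower and 110 higher in the 1-cell library, with a median change of -0.30. Among the 110, 108 were listed at exactly 0 in the oocyte, and 1 of the 110 had a gene symbol: RTKN2, at 21.8 against 4.36 RPKM (4.99-fold, 4.58 to 5.43). The next genes with a symbol, short of the rule, were sde2 (8.38 against 1.5 RPKM, 5.58-fold, 4.68 to 6.69) and the cytokinesis regulator RACGAP1 (5.95 against 1.07 RPKM, 5.58-fold, 4.70 to 6.66). Alternatives chosen after seeing the data moved both the count and the share of higher genes. Genes with a symbol alone gave 300 changed genes, 0.33% of them higher, in place of 463 with 23.8% higher. The 4-cell library in place of the 1-cell library gave 736 with 51.5% higher. There the share moved because more genes were higher, not because fewer were lower.

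**Figure D2:**
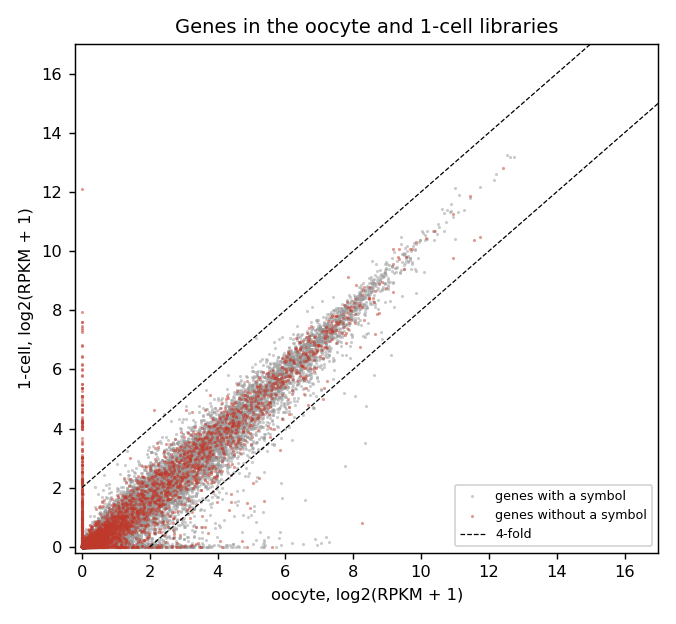
The value log2(RPKM + 1) of each gene in the oocyte library (horizontal axis) and in the 1-cell library (vertical axis), with genes that have a symbol and genes that have none in separate colours and dashed lines at 4-fold. Of the 110 genes above the upper line, 108 lie at 0 in the oocyte library.

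The 128-cell and 1-cell libraries were compared to follow transcripts through cleavage. Among the genes with the largest rise were the chromatin insulator protein CTCF (ENSDARG00000056621), which went from 0.89 to 107 RPKM (121-fold, 103 to 143), and CDK9, the kinase of transcription elongation, from 0.53 to 83.8 RPKM (157-fold, 113 to 224). Further ones were DKC1, of small nucleolar ribonucleoproteins, from 2.37 to 150 RPKM (63.3-fold, 54.5 to 74.0), and tut4, which adds uridine to mRNA tails, from 1.41 to 76.6 RPKM (54.3-fold, 45.3 to 65.7). Lower in the 128-cell library were BUB3, of the spindle checkpoint (ENSDARG00000075883, 484 to 3.85 RPKM, 126-fold, 114 to 139), and the spindle protein tacc3 (667 to 12.5 RPKM, 53.3-fold, 51.6 to 55.0). So were the kinase MELK (67.1-fold, 62.5 to 72.2) and the cell division gene cdca9 (55.6-fold, 50.3 to 61.6). ZAR1L, an oocyte RNA-binding protein, was 63.5-fold lower (59.6 to 67.7) and TRDMT1, a tRNA methyltransferase, 139-fold lower (115 to 170). Also higher were SEC13, CWC25, hdgfl2, arhgef18a, znf1035 and mkrn4 (571 against 17 RPKM, 33.6-fold, 31.8 to 35.5). Also lower were nupr1a, DCK, PEF1 and zufsp.

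The germ plasm list had 9 of 20 members higher and 1 lower. Higher were buc, the Balbiani body organiser (10.1 to 200 RPKM, 19.8-fold, 18.6 to 21.1), TDRD1 and TDRD6 (13.2-fold, 11.9 to 14.7, and 15.9-fold, 14.8 to 17). The lower one was DAZL (6.31-fold, 6.17 to 6.46). The list median of 1.75 sat at the 97.0 percentile of random lists. Regulators of mRNA stability had 12 higher and 2 lower of 28. The higher included PUM3 (43.1-fold, 35.2 to 53.3), IGF2BP3 (18.6-fold, 16.8 to 20.6) and the m6A reader YTHDF2 (17.5-fold, 15 to 20.5), and the lower included BTG4 (6.02-fold, 5.90 to 6.15). Of 18 histone modifiers 6 were higher and 1 lower. EZH2, of Polycomb repression, was 16.5-fold higher (14.4 to 18.8), and the lower gene, setdb1a, was 4.28-fold lower (4.17 to 4.39). Of 10 genes of DNA methylation 3 were higher, including dnmt3bb.2 (19.8-fold, 17.1 to 22.9). Cell cycle genes split, with 7 higher and 6 lower of 33. MCM5, of the replicative helicase (38.6-fold, 32.6 to 46.0), was among the higher, and AURKB (11.4-fold, 11.1 to 11.6) and MAD2L1 (7.82-fold, 7.60 to 8.04), of mitotic control, among the lower. The activator sox19b was 19.5-fold higher (18.6 to 20.4). Mitochondrially encoded genes were lower in 8 of 13 (median -2.30) and ribosomal proteins had a median of -0.96 with none past the rule. Both medians lay below all random lists and below the median of 1.13 for all genes.

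In all, 3174 genes were higher and 300 lower of 12336 measured, so that 91.4% of the changed genes were higher. Median ratio scaling gave 1664 higher and 774 lower genes (68.3% higher) and moved the median of all genes by -0.55. Of the 3174 genes, 211 already passed the rule in the 4-cell library, 2631 (82.9%) in the 16-cell library and 2473 (77.9%) in the 64-cell library. In the 16-cell library 66.2% of the 3174 were higher than in the 64-cell library, as were 57.8% of the other measured genes. Among the 3174, 3163 were above 0 in the 1-cell library, and 76.3% were lower in the 1-cell library than in the oocyte. That share is tilted by construction, since the genes were chosen for 1-cell values below those of the 128-cell library. Genes at large were lower in the 1-cell library too, with a median change from the oocyte of -0.30 over the 10373 measured. The steps between neighbouring stages held 224 higher and 37 lower genes from 1-cell to 4-cell, 1343 and 74 from 4-cell to 16-cell, and 10 and 115 from 16-cell to 64-cell. Later steps held 3 and 11 from 64-cell to 128-cell, 1 and 2 from 128-cell to 256-cell, and 17 and 0 from 256-cell to 1000-cell. With the 4-cell library in place of the 1-cell library, 880 genes in place of 3474 changed.

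Across the 7 libraries from 1-cell to 1000-cell, expression was fitted against the log2 of the number of cells, to ask which transcripts rose or fell steadily while the embryo divided. CTCF rose by 0.64 (SE 0.070) log2 units per doubling of cell number and pprc1, a coactivator of mitochondrial genes, by 0.62 (SE 0.089). CDK9 rose by 0.60 (SE 0.11), the RNA helicase gene setx by 0.57 (SE 0.064), and trim35-29, znf1035 and hdgfl2 by 0.60, 0.60 and 0.59 (SE 0.047, 0.054 and 0.092). BUB3 fell by 0.87 per doubling (SE 0.082), the kinetochore motor cenpe fell by 0.64 (SE 0.053) and the replication factor CDC45 fell by 0.63 (SE 0.050). In addition tacc3 fell by 0.62 (SE 0.078), and TOP2A, which untangles DNA, fell by 0.59 (SE 0.050). Each of these 12 had an adjusted limma p between 0.00103 and 0.00275. All 63 ribosomal protein genes that passed, of 69 tested, fell, such as RPL7 (fell by 0.18, SE 0.030), and 64 passed when adjusted over the list alone. In the same way 12 of 13 mitochondrially encoded genes fell (13 adjusted over the list alone).

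Over all 12720 genes tested, 6699 rose and 1165 fell, and the counts by list stand against that background. Regulators of mRNA stability rose in 14 and fell in 5 of 28 (15 and 6 adjusted over the list alone). Neither this list nor the proteasome list below exceeded the share of rising genes among all genes. PUM3 rose by 0.55 (SE 0.058), and CNOT7, of the deadenylase complex, fell by 0.12 (SE 0.042). Histone modifiers rose in 12 and fell in 2 of 18, and germ plasm genes rose in 12 and fell in 4 of 20, with the same counts adjusted over the list alone. Proteasome genes rose in 18 and fell in 1 of 38 (17 and 1 adjusted over the list alone). Cell cycle genes rose in 9 and fell in 13 of 33 (9 and 13 adjusted over the list alone), and nuclear oxidative phosphorylation genes rose in 15 and fell in 24 of 72 (15 and 23 adjusted over the list alone). For the other lists the numbers rising and falling are given over all genes and then, in parentheses, adjusted over the list alone. They were 8 and 8 of 30 for egg coat and oocyte factors (8 and 8) and 5 and 2 of 17 for maternal axis and activation factors (5 and 2). For meiosis they were 5 and 0 of 8 (5 and 1), for heat shock and stress 5 and 0 of 12 (4 and 0), and for housekeeping references 3 and 3 of 14 (2 and 3). DNA methylation had 3 and 3 of 10 (4 and 3) and histone variants 2 and 2 of 6 (2 and 2). Axoneme and tail genes had 2 and 1 of 7 (1 and 1), BMP, FGF and organizer signalling 2 and 1 of 5 (2 and 1), and the enveloping layer 1 and 1 of 6 (1 and 1).

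In all, 7864 of 12720 genes passed, 6699 rising and 1165 falling, so that 85.2% rose, against 5151 rising and 2259 falling (69.5%) under median ratio scaling. Without the 1-cell library 2015 genes passed, and 1911 of the 7864 passed with every library left out in turn. A monotonic course was rarer than a slope: 484 of the rising genes never fell between neighbouring libraries and 113 of the falling genes never rose.

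As a second view, the mean log2(RPKM + 1) of each of 22 lists was correlated with log2 cell number over the same 7 libraries, with exact two-sided permutation tests over 5040 pairings. These tests ask whether a list's mean changed with cell number at all, not whether it changed more than the other genes did. Ribosomal proteins fell on average (r = -0.975, exact p = 0.00040, adjusted p = 0.0044, Spearman rho = -0.96, exact p = 0.0028, adjusted p = 0.020). Their r was -0.96 without the 1-cell and 4-cell libraries, the 2 farthest from the median log2 cell number. The mRNA stability list rose (r = 0.93, exact p = 0.00020, the smallest these permutations can give, adjusted p = 0.0044, rho = 1.00, exact p = 0.00040, adjusted p = 0.0087, r = 0.98 without those 2 libraries). So did histone modifiers (r = 0.91, exact p = 0.00079, adjusted p = 0.0058, rho = 0.93, exact p = 0.0067, adjusted p = 0.030, r = 0.88 without them). Of the 22 lists, 11 passed by r, 9 rising and 2 falling, and 5 passed by rho. Among the other 8 that passed by r, the relation rested on these 2 early libraries for 5. They were germ plasm (r = 0.82, exact p = 0.014, adjusted p = 0.034, rho = 0.64, exact p = 0.14, adjusted p = 0.22, r = -0.16 without them) and mitochondrially encoded proteins (r = -0.82, exact p = 0.011, adjusted p = 0.033, rho = -0.71, exact p = 0.088, adjusted p = 0.19, r = -0.056 without them). Heat shock and stress was also among the 5 (r = 0.84, exact p = 0.012, adjusted p = 0.033, rho = 0.71, exact p = 0.088, adjusted p = 0.19, r = 0.22 without them). So were maternal axis factors (r = 0.77, exact p = 0.021, adjusted p = 0.041, rho = 0.68, exact p = 0.11, adjusted p = 0.22, r = 0.11 without them) and DNA methylation (r = 0.79, exact p = 0.011, adjusted p = 0.033, rho = 0.71, exact p = 0.088, adjusted p = 0.19, r = 0.24 without them). Under median ratio scaling these last 2 turned to r = -0.22 and -0.75. Of the remaining 3, meiosis rose (r = 0.94, exact p = 0.0022, adjusted p = 0.012, rho = 0.96, exact p = 0.0028, adjusted p = 0.020, r = 0.77 without them). So did axoneme and tail (r = 0.85, exact p = 0.0038, adjusted p = 0.017, rho = 0.93, exact p = 0.0067, adjusted p = 0.030, r = 0.58 without them) and mesendoderm (r = 0.81, exact p = 0.020, adjusted p = 0.041, rho = 0.79, exact p = 0.048, adjusted p = 0.15, r = 0.68 without them). The means of these 3 lists stayed below 1.5 log2 units in all 7 libraries. In any 1 of them at most 8 meiosis, 7 axoneme and 3 mesendoderm genes reached 1 RPKM, so most members lay near the floor. The other 11 lists did not pass, the nearest being the proteasome (r = 0.81, exact p = 0.028, adjusted p = 0.052, rho = 0.64, exact p = 0.14, adjusted p = 0.22, r = 0.053 without the 2 early libraries). Their adjusted p for r reached 0.93 for nuclear oxidative phosphorylation. With the median over each list's members in place of the mean, 3 lists passed, ribosomal proteins, mRNA stability and histone modifiers. Under median ratio scaling 8 passed, without the axoneme, germ plasm, mesendoderm, heat shock, maternal axis and DNA methylation lists and with histone variants, cell cycle genes and housekeeping references falling.

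**Figure D3:**
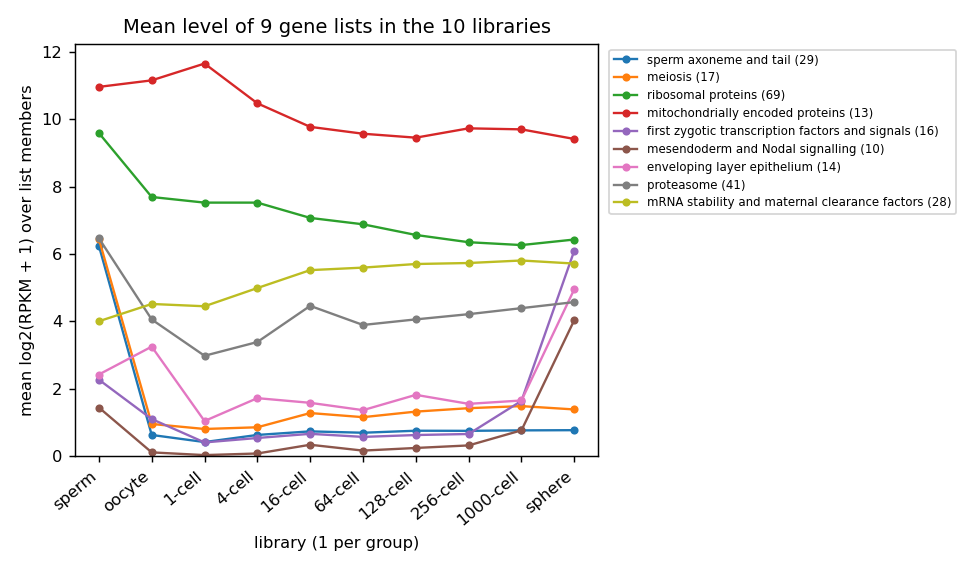
Mean log2(RPKM + 1) over the members of 9 gene lists (vertical axis) in each of the 10 libraries (horizontal axis), 1 library per stage, with 1 line per list. The ribosomal protein line goes from 7.53 in the 1-cell library to 6.27 in the 1000-cell library, and the line of first zygotic genes from 1.64 in the 1000-cell library to 6.10 in sphere.

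The 1000-cell library was compared with the 128-cell library because the zebrafish embryo is known to begin broad transcription of its own genome near that stage. The transcription factor genes klf17, of the Krüppel-like family, and irx7, an Iroquois homeobox gene, were the most increased with a symbol. The gene klf17 went from 0.51 to 12.7 RPKM (24.8-fold, 19.8 to 31.6) and irx7 from 0.036 to 5.51 RPKM (153-fold, 59.5 to 565). The gene nnr went from 1 to 186 reads (4.12 RPKM, 245-fold, 43.5 to 9744). Of 11 measured genes on the list of first zygotic transcription factors and signals 3 were higher, these same genes, and the list median of 1.18 lay above all random lists. Below the rule on that list, the homeobox gene mxtx2 stood at 1.79 against 0.024 RPKM (74.3-fold, 25 to 364). SOX3 stood at 3.16 against 0.52 RPKM (6.05-fold, 4.78 to 7.72) and grhl3, of the Grainyhead family, at 1.11 against 0.067 RPKM (16.6-fold, 10.4 to 28.0). At these levels the added 1 RPKM holds the log2 change under 2.

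Besides these, tmsb5, a thymosin (5.81 to 34.5 RPKM, 5.94-fold, 5.26 to 6.73), and lrrc59 (4.57-fold, 4.32 to 4.84) were higher. The nucleolar gene surf6 (4.55-fold, 4.19 to 4.93) fell just short of the rule, and rsl1d1, hrob, MIX23, arpc4l and DDX49 came next with changes of 1.73 to 1.88. Of these, lrrc59, surf6 and DDX49 were not new after the 128-cell stage. They stood at 42.3, 39.1 and 19.4 RPKM in the 16-cell library, against 34.5, 24.8 and 9.43 in the 1000-cell library. The genes klf17 and irx7 stood at 0.35 and 0.094 RPKM in the 16-cell library. On the lower side krt91 (-1.84), krt5 (-1.74), hdlbpb (-1.58), icn (-1.39), kif15 (-1.38), tubb5, TRIM36, CPOX, lemd1 and dip2cb stayed short of the rule. The first 2 and icn stood at 12.6, 13.7 and 9.05 RPKM in the 128-cell library, against 0.093, 0.20 and 0.26 in the 1-cell library. The enveloping layer list had a median of -0.79 with 1 of 9 genes higher, klf17, which is also on the first zygotic list. That fall starts from a high 128-cell library. The mean log2 value over 14 expressed members was 1.36 at 64-cell, 1.82 at 128-cell, 1.55 at 256-cell and 1.65 at 1000-cell. BMP, FGF and organizer signalling had a median of 0.54 over 7 genes with none past the rule. In all, 18 genes were higher and 1 lower of 12749. Against all 5 libraries from 1-cell to 128-cell at once, 16 genes were at least 4-fold above the highest in the 1000-cell library and 0 in the 256-cell library, and all 16 were so in sphere as well. Counts this small moved with the settings, from 19 changed genes to 56 with 0.1 RPKM added, 0 with 5 RPKM added, 9 with only genes that have a symbol, and 99 with the 64-cell library in place of the 128-cell library.

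Sphere was compared with the 1000-cell embryo to see what was expressed at this later stage. The genes with the largest rise were akap12b, a kinase anchor (242 against 0.55 RPKM, 440-fold, 390 to 499), krt18a.1, a keratin of the enveloping layer (137 against 0.11 RPKM, 1207-fold, 732 to 2157), and asb11 (1285-fold, 718 to 2576). Further ones among the 10 with the largest rise were the cofactor vgll4l (442-fold, 316 to 639), the small heat shock gene HSPB1 (126-fold, 108 to 148) and nnr (422 against 4.12 RPKM, 103-fold, 88.8 to 119). The T-box gene tbx16, of mesoderm, went from 0.028 to 53.8 RPKM (1891-fold, 1028 to 3943). The BMP antagonist gene chrd went from 0.049 to 27.3 RPKM (562-fold, 322 to 1089), and the notochord gene noto from 0.50 to 42.8 RPKM (86.2-fold, 61.8 to 124). Among the lower genes were TDRD6, of germ plasm (7.82-fold, 7.56 to 8.08), sh2d5 (10.9-fold, 10.3 to 11.6), and sc:d217 (46.7-fold, 32.3 to 70.0). Others were SSH2 (8.0-fold, 7.67 to 8.34), ZBTB1 (10.6-fold, 9.46 to 11.9), CCNI2, micall2b, LUZP1, dnajc5ga and TENT4A, a poly(A) polymerase (6.41-fold, 6.18 to 6.66).

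Of 18 measured first zygotic factors 17 were higher (median 4.63). They included the SoxB1 gene sox19a, higher 72.8-fold (61.9 to 86.2), mych 44.2-fold (40.4 to 48.5) and grhl3 84.5-fold (74.4 to 96.4). The genes klf17 and irx7 were higher by a further 7.04-fold (6.66 to 7.43) and 7.42-fold (6.74 to 8.18). Enveloping layer genes were higher in 12 of 16 (median 3.13), including krt4 (263-fold, 194 to 367) and the claudin cldne (267-fold, 175 to 432). Mesendoderm and Nodal genes were higher in 11 of 15 (median 2.65). Among them were the Nodal ligand ndr1, higher 7.06-fold (5.86 to 8.56), its antagonists lft1 and lft2 17.1-fold (12.8 to 23.3) and 13.3-fold (10.4 to 17.1), and GSC 27.5-fold (20.9 to 37.0). BMP, FGF and organizer genes were higher in 7 of 14 (median 1.98), with bmp7a 45.2-fold (37.0 to 56.0) and the FGF feedback phosphatase DUSP6 20.3-fold (17.7 to 23.2). These 4 medians lay above all random lists. Histone variants were higher in 2 of 7, h2ax (6.45-fold, 5.48 to 7.63) and hist2h3c (26.1-fold, 17.4 to 41.1). Of 38 cell cycle genes 4 were higher, among them the inhibitors cdkn1ca (30.3-fold, 24.3 to 38.4) and cdkn1a (0.14 to 4.21 RPKM). Germ plasm genes had a median of -0.69 with 1 of 20 lower, TDRD6. CNOT7, at 5.78-fold lower (5.33 to 6.28), was the 1 mRNA stability gene of 28 past the rule. In all, 568 genes were higher and 58 lower of 13983, around a median of -0.03. Of the 564 genes at least 4-fold above the highest of the 5 libraries from 1-cell to 128-cell, 454 were below 1 RPKM in all 5 and in the oocyte. The median recovered length of the 564 was 1504 bases against 2055 for all genes at 1 RPKM or more in sphere.

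**Figure D4:**
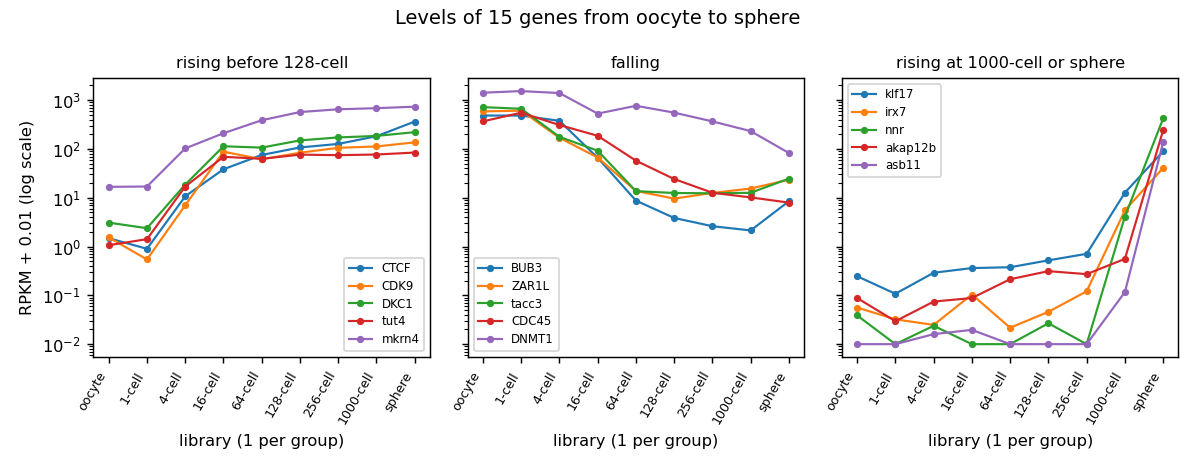
RPKM + 0.01 (log axis) of 15 named genes in each library from oocyte to sphere (horizontal axis), 1 library per stage. CTCF goes from 0.89 RPKM in the 1-cell library to 365 in sphere, BUB3 from 484 to 8.50, and nnr from no read to 422.

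Sphere was also compared with the 1-cell embryo to give the sum of both periods. The genes most increased were nnr, without a read in the 1-cell library (422 RPKM, at least 3379-fold), marcksl1b, a substrate of protein kinase C (393 against 0.22 RPKM, 1774-fold, 1037 to 3331), and ID1 (288 RPKM against 1 read). Next were akap12b (242 RPKM against 5 reads), CTCF (365 against 0.89 RPKM, 410-fold, 350 to 485), asb11 (at least 2505-fold) and krt18a.1 (137 RPKM against 1 read). After them came the Hairy-related gene her5 (125 against 0.059 RPKM), vgll4l (119 RPKM against 1 read) and mych (451-fold, 305 to 697), and on the list of first zygotic factors sox19a reached 69.4 RPKM (at least 1895-fold). The genes most decreased were DCK, a nucleoside kinase (259-fold, 183 to 383), CDC45 (69.9-fold, 66.2 to 73.7), and BUB3 (56.9-fold, 53.1 to 61.1). Others were the nucleoside carrier SLC29A2 (53.4-fold, 50.2 to 56.8), cenpe (53.6-fold, 51.4 to 55.9), TRDMT1 (76.0-fold, 65.3 to 89.1), PEF1, sh2d5, MELK and RNF7. First zygotic factors were higher in 17 of 18 (median 5.70), and enveloping layer genes in 14 of 16 with epcam lower (7.21-fold, 7.15 to 7.27). Mesendoderm genes were higher in 13 of 15, BMP, FGF and organizer genes in 11 of 14, and proteasome genes in 19 of 37 (median 2.05). Also lower were the germ cell RNA-binding gene DAZL (29.7-fold, 28.3 to 31.2), cldnd (13-fold, 12.8 to 13.1) and DNMT1 (1536 to 82.6 RPKM, 18.6-fold, 18.4 to 18.8). The de novo methyltransferase gene dnmt3bb.2 was 48.3-fold higher (42.0 to 56.0). Nuclear oxidative phosphorylation genes had a median of 0.09, which turned to -0.52 under median ratio scaling.

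In all, 4320 genes were higher and 623 lower of 13769, with a median of 1.25. Of the changed genes 87.4% were higher. Median ratio scaling gave 3029 higher and 1196 lower genes (71.7% higher) and moved the median of all genes by -0.39. With the 4-cell library in place of the 1-cell library 2846 genes changed, in place of 4943.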

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

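The symbol-only, thinned, neighbour-library, voom and 64-cell-on settings were chosen after the data were seen. Of 95 alternative values of the main counts, 63 lay within 1.5 times the count reported. Across the 6 comparisons, in the order sperm against oocyte, 1-cell against oocyte, 128-cell against 1-cell, 1000-cell against 128-cell, sphere against 1000-cell and sphere against 1-cell, the changed genes numbered 7040, 463, 3474, 19, 626 and 4943. With 0.1 RPKM added they were 10871, 1244, 5692, 56, 1254 and 7601, and with 5 RPKM added 3224, 128, 1229, 0, 206 and 2120, because the added value by construction shrinks changes of low genes. The 2-fold rule, a looser threshold, gave 12899, 2003, 7765, 492, 2003 and 9688. Rescaling each library to a total of 1000000 raises every value beside the added 1, by more where the RPKM total was lower (395402 in 1000-cell, 503041 in 1-cell). With it, 1-cell against oocyte, 1000-cell against 128-cell and sphere against 1000-cell gave 795, 37 and 1016. Genes with a symbol alone, a smaller set, gave 300, 9 and 377 for these 3. The 4-cell library in place of the 1-cell library gave 736, 880 and 2846 against oocyte, 128-cell and sphere, and the 64-cell library in place of the 128-cell library gave 99 against 1000-cell, where the cause was not tested. The trend count of 7864 ran from 2015 without the 1-cell library to 9909 without the 16-cell library, and was 4751 from 1-cell to 128-cell and 4387 from 64-cell on, with fewer libraries in each fit. Of 22 lists, 11 passed by r and 3 with the median over the members; the cause was not tested.

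Median ratio scaling, which changes the scale of whole libraries, moved the median of all genes by -0.21, 0.18, -0.55, -0.12, 0.07 and -0.39 in the 6 comparisons. It turned 5 results round, and why some list values moved further than these medians was not tested. The ribosomal protein median became 0.11 in 1-cell against oocyte, the maternal axis median -0.15 in 128-cell against 1-cell and the nuclear oxidative phosphorylation median -0.52 in sphere against 1-cell, and the trend r became -0.22 for maternal axis factors and -0.75 for DNA methylation. Rescaling to 1000000 moved the median of all genes by 0.33, 0.49 and 0.63 in sperm against oocyte, 128-cell against 1-cell and sphere against 1-cell, and leaving out the 20 most abundant genes by 0.11 in the last. Of 835 alternative list medians 767 were the same within their interval, 65 moved and 3 turned. Which scaling is right cannot be settled without spiked-in RNA, since RPKM gives shares of a library and not molecules per embryo. No paired analysis was possible because each stage has 1 library. Depth limits genes under about 0.079 RPKM, for a gene of 1 kilobase, in the 1-cell library, where 3 reads are not reached.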

Other observations

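The tests of the genes at 0 in the oocyte library, of scaling, of the tissue sources of the sperm library and of abundant genes, the 16-cell values of this paragraph and the counts of rising genes in single libraries were chosen only after the results were seen. The 16-cell library stood apart from the libraries on either side. In it 1240 genes were at least 2-fold above both the 4-cell and the 64-cell library and 300 were at least 2-fold below both, against 64 and 54 for the 4-cell, 3 and 9 for the 64-cell, 10 and 6 for the 128-cell and 5 and 5 for the 256-cell library. The gene fbxo5, an inhibitor of the anaphase-promoting complex, stood at 142 RPKM between 2.1 in the 4-cell and 4.94 in the 64-cell library, and the translation factor gene EIF2S2 at 158 between 2.46 and 8.48. The oocyte kinase gene MOS stood at 102 between 9.07 and 7.18, the ferritin gene fth1a at 534 between 35.0 and 54.6, and the oocyte growth factor bmp15 at 43.9 between 3.82 and 5.26. Of 22 gene lists, 9 had their highest mean of the 1-cell to 1000-cell libraries there, with means of 4.50 for nuclear genes of oxidative phosphorylation, 4.46 for the proteasome and 5.98 for the cell cycle. Across genes, the change between the 64-cell and 16-cell libraries had a Spearman rho of 0.62 with the change between the 128-cell and 1000-cell libraries and of -0.30 with that between oocyte and 1-cell.

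DNMT1, which copies methylation after replication, stood at 1536 RPKM in the 1-cell library, 367 in the 256-cell, 232 in the 1000-cell and 82.6 in the sphere library. It was among 35 genes in sphere at least 4-fold below the lowest of the 5 libraries from 1-cell to 128-cell, with TENT4A, CPEB1, CNOT7, sh2d5 and ZBTB1 also among them. No gene met that rule in the 256-cell or 1000-cell library.

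The first pattern weighed is the rise of 3174 genes at least 4-fold from the 1-cell to the 128-cell library. Gene length was not the whole cause of the rise: 3113 genes rose after correction for the median change of genes of like length. In the trend, 1 of 100 stage orders, the real one, called as many as 7864 genes (at most 5007 in the others). Without the 20 most abundant genes 3443 genes rose. That setting also brings the libraries to a common total, so it cannot decide on those 20 genes alone. The RPKM totals were 503041 in the 1-cell and 416132 in the 128-cell library. With every library thinned to 1 depth 3177 genes rose. Thinning lowers the reads but leaves the expected RPKM as it was, so this count could move little and does not decide on depth. How much of the rise is due to scaling cannot be told apart from stage, since 1664 genes rose and 774 fell under median ratio scaling, which takes the median gene of those at 1 RPKM or more in both libraries as unchanged, and spiked-in RNA was not analysed here. A part for length (Spearman rho of 0.141 across genes), for RNA without a poly(A) tail (median change of 0.30 over 4 genes, too few to decide) and for a difference between libraries that does not follow stage (rho of 0.117 with the 16-cell against 64-cell change) cannot be told apart from stage either, as these values fall between the limits set beforehand. Of the 3174 genes, 1767 were at 1 RPKM or more in the 1-cell and 2192 in the oocyte library, and 77.9% had risen in the 64-cell library (82.9% in the 16-cell library, which stood apart), so for a part of them longer poly(A) tails on stored transcripts are a candidate explanation, untested like new transcription, that libraries of the same stages made without poly(A) selection would decide.

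The second pattern is the 153 genes at exactly 0 in the oocyte library with at least 1 RPKM in all 8 embryo libraries, such as ENSDARG00000040344. None of the 153 had a symbol, against 18.2% without a symbol among the 8119 genes at 1 RPKM in every embryo library, and no other library had more than 14 such genes. Low depth is argued against by the 528 reads expected in the median gene. Values left out of the oocyte column for some gene IDs may account for them (153 against 14), although 1321 of 1474 genes without a symbol kept a value above 0, and reads shared between near-identical copies or a variant in the oocytes' parents were not tested. No biological explanation was tested, and 108 of the 110 genes higher in the 1-cell library than in the oocyte fall under this doubt.

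The third pattern is the meiosis and testis transcripts of the sperm library. RNA of testis cells other than sperm may be a source, since the median of the 15 testis somatic genes was 101 RPKM in sperm and 12 were at least 4-fold above the oocyte, with insl3 at 430 and gsdf at 312 RPKM; 5 of the 15 are on the follicle list and 4 reach 1 RPKM in the oocyte. Blood, muscle and liver are argued against as large sources by list medians of at most 0.929 RPKM. A small share is not excluded, as 8 of 17 blood, 7 of 17 muscle and 11 of 27 liver and yolk genes reached 1 RPKM. Pancreatic proteases such as prss59.1 at 483 RPKM were on no list and their source was not tested. Whether meiotic transcripts such as those of HORMAD1 and SYCP3 came from mature sperm or from earlier germ cells in the same preparation stays open, as the labels name no sort or wash.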
